A study of Mus musculus with 6 samples.

How the data were processed

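Total RNA of interscapular brown adipose tissue was sequenced after library preparation with the TruSeq RNA Sample Prep kit v2, per the labels' protocols. The submitters' processing notes name CASAVA and bcl2fastq, without versions. The aligner, the genome build and the annotation are not given in the sources used here. The deposited table gives RPKM values made by the authors for 168326 transcript rows in 6 libraries, written with decimal commas. No header names the unit. It was worked out from the deposited values of 46002 Ensembl transcripts with a known length. Low products of value and length fell mostly on whole multiples of a single step per library. Only low products, 11004 to 11546 per library, were checked. Of the low products, 95.8% to 96.2% were whole within a tolerance of 0.1 reads. The steps imply 15800000 to 18000000 reads per library, and similar depth in all libraries gives similar precision. Between 13.6% and 15.2% of reads lay on 11 mitochondrial transcripts.

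Rows with no gene identifier (23170, or 13.8%) were left out of the comparison of genes. The remaining rows belong to 29072 genes. A single row was kept per gene: a RefSeq row where there was one, then an Ensembl row, then any other, and the row with the highest mean over all 6 libraries within a kind. The plan written before the data were examined was to sum the rows of a gene. This was changed before any test because the transcripts of a gene share reads, and the sum was run as an alternative. Gene identifiers of 24525 genes (84.4%) matched a RefSeq gene table of mouse assembly GRCm38.p6, which served only for names and for which genes neighbour each other. No coordinates are printed because the authors' build is not known. Gapdh and Ppia are listed at 0 in every library, so genes with near-identical copies are uncertain in this table, and a gene listed at 0 need not be silent. Reads of overlapping or antisense genes cannot be separated because the use of strand is not stated.

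The table holds no counts, so the count model planned as the main test was replaced by the fallback fixed with it. Values were transformed to log2(RPKM + 1), genes with a mean of at least 1 RPKM in either group were kept, and limma 3.58.1 in R 4.3.3 was run with an intensity trend on all 6 libraries, with genotype as the only factor. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Errors are SD over 3 libraries for levels and moderated standard errors for log2 changes. On simulated data with 200 changed genes among 11143, modelled on this comparison, 91% of changes of 0.58 on the log2 scale were recovered. Of changes of 1 and of 2, 100% were recovered each, and 5.4% of calls were unchanged genes. The changed genes had a wildtype mean of at least 2 RPKM. Every simulated gene had the same length and biological spread, and genes varied independently. Simulated changes went up or down at random, and no shift common to many genes was simulated. The shares recovered and wrongly called may not hold for the real genes, which differ in spread and move together. They do not cover errors from such a shift between the groups.

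Before the data were examined, 33 gene lists were fixed. They cover brown fat function, fuel metabolism, stress responses, the clock, and markers of other cell types that a dissected depot can hold. The 30 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Of the list symbols, 12 had no gene in the table, among them 6 of the mitochondrially encoded genes. Genes were named by a rule fixed in advance. It takes Ucp1, the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 5 RPKM, leaving out predicted genes, clones and pseudogenes. It also takes from each list up to 3 called members with the smallest adjusted p, or the 1 member with the smallest p where none passed, and every member of lists with under 5 tested. Up to 10 called genes within 10 Mb of Ucp1 could be named in the closing section. Genes named outside this rule are said to be so where they are named. A gene that the rule takes from the fatty acid oxidation list is not reported here.

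A gene was said to follow the muscle list among wildtype libraries when its value, plus 0.1 RPKM, was at least 2 times lower in the wildtype library with the least Acta1 than in each other wildtype library. Alternatives changed the scaling, the filter, the pseudocount, the threshold, the rows used per gene, the replicates and the model. Limma-voom was run on reads recovered from Ensembl rows for genes with at least 10 reads in 3 libraries. No library duplicated another: 2 genes above 0 held identical values in wildtype replicates 2 and 3, and 0 in each other pair.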

Results

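RNA was measured in interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades, of mice of the C57BL/6J strain. Of the 6 libraries, 3 came from mice without a working Ucp1 gene (knockout) and 3 from wildtype mice. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. The deposited values were RPKM, reads scaled to transcript length and to the library's read total. The spacing of low values implied 16000000, 15800000 and 18000000 reads for knockout replicates 1, 2 and 3, and 16300000, 16200000 and 16300000 reads for wildtype replicates 1, 2 and 3. The correlation of log2 values across genes, which are not independent replicates, was 0.992 to 0.994 within the knockout group, 0.984 to 0.990 within the wildtype group and 0.969 to 0.980 between the groups.

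The design asks how brown fat transcripts differ between Ucp1 knockout and wildtype mice, and the targeted gene was examined before any other. Ucp1 encodes the uncoupling protein of brown fat mitochondria, which releases the proton gradient as heat. Its level was 379 ± 8.83 RPKM in knockout brown fat and 2653 ± 814 RPKM in wildtype brown fat (mean ± SD, n = 3 each). Ucp1 was thus 7.01-fold lower in the knockout libraries. The knockout libraries held 375, 389 and 372 RPKM of Ucp1, and the wildtype libraries 3096, 1714 and 3151 RPKM, so wildtype replicate 2 lay below the other wildtype libraries. The log2 change of Ucp1 was -2.75 (SE 0.21, limma adjusted p = 0.000408), and the lowest wildtype library lay above every knockout library. The table gives 3 transcript rows for Ucp1, and each was lower in the knockout group. These rows cover whole transcripts, so the remaining Ucp1 reads do not show which part of the gene was deleted.

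Among 11541 genes tested with limma, 894 passed an adjusted p of 0.05, of which 808 were higher and 86 lower in knockout brown fat. With library scaling by the median of ratios, 645 genes passed, 492 higher and 153 lower, so the share of higher calls fell from 90.4% to 76.3%. The median log2 change over all tested genes was 0.076 as deposited and -0.007 after that scaling. A log2 change of at least 1 was reached by 187 of the higher genes and 9 of the lower genes. The knockout and wildtype values as deposited did not overlap for 29.4% of tested genes. Chance gives 10% if no shift common to many genes separates the groups. The median log2 change of 0.076 points to such a shift, which can raise this share. The share after scaling was not computed. Without knockout replicate 1 the count was 477, and without knockout replicate 2 it was 457. Fold changes from limma are on the log2(RPKM + 1) scale, which understates the change of genes with low values.

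The 8 largest rises in knockout brown fat taken by the naming rule were all genes of skeletal muscle fibres. Ckm, the muscle creatine kinase, rose from 22.3 ± 15.3 RPKM in wildtype to 253 ± 26.9 RPKM in knockout (SD, n = 3 each), a log2 change of 3.81. Acta1, the actin of skeletal muscle thin filaments, rose from 37.3 ± 25.5 to 397 ± 47.6 RPKM. Pvalb (parvalbumin, a calcium buffer of fast fibres), Tnnc2, Tnni2 and Tnnt3 (fast troponin subunits), Atp2a1 (the calcium pump of the sarcoplasmic reticulum) and Mylpf (a fast myosin light chain) rose by log2 changes of 3.58 to 3.68. The muscle list members with the smallest adjusted p were Myl1, a myosin light chain (28.4 ± 6.65 to 105 ± 5.04 RPKM), and the giant sarcomere proteins Neb (0.562 ± 0.373 to 5.02 ± 0.387 RPKM) and Ttn (0.461 ± 0.324 to 4.23 ± 0.517 RPKM). All 20 tested members of the skeletal muscle list rose, whether adjusted over all genes or over the list alone, with a median log2 change of 3.23. The list's camera adjusted p was 9.85e-20 at a preset correlation, and the adjusted p = 0.669 with an estimated correlation. Directional fry gave an adjusted p = 0.0459 for the list. Muscle RNA also differed among wildtype libraries: Acta1 stood at 46.5, 56.95 and 8.54 RPKM in wildtype replicates 1, 2 and 3, against 425, 424 and 342 RPKM in the knockout libraries. The median of the muscle list was 70.3 to 94.7 RPKM in the knockout libraries and 2.54 to 12.0 RPKM in the wildtype libraries, so the amount of muscle RNA differed with genotype.

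**Figure D1:**
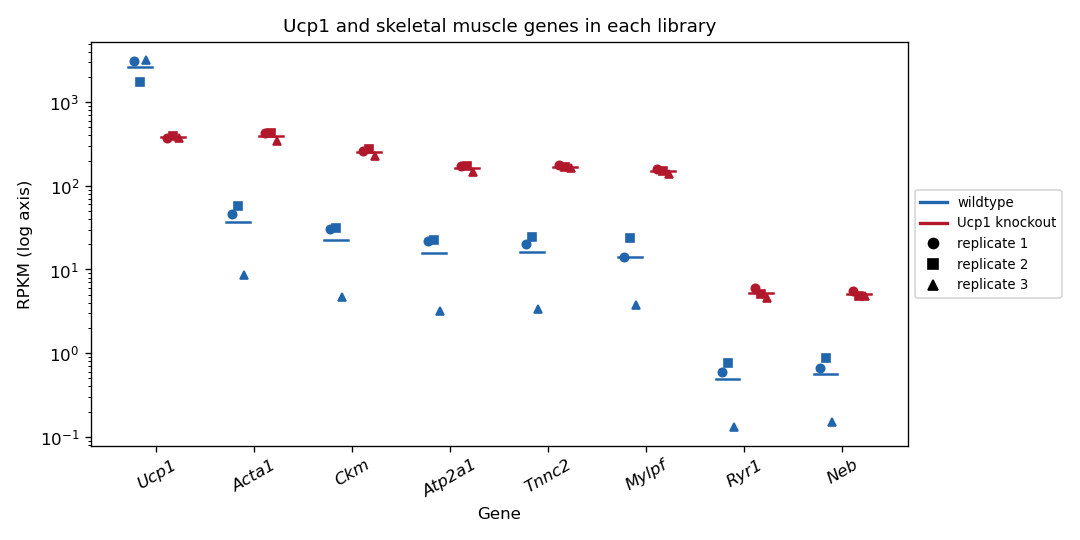
RPKM of Ucp1 and 7 skeletal muscle genes in each library on a log axis, with wildtype in blue, Ucp1 knockout in red, a symbol for each replicate and a horizontal line at each group mean. Ucp1 stood at 2653 RPKM in wildtype and 379 RPKM in knockout on average, while Acta1 stood at 37.3 and 397 RPKM, with wildtype replicate 3 the lowest library for each of the 7 muscle genes.

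The largest falls after Ucp1, among genes the naming rule takes (mean of at least 5 RPKM in the higher group), were spread over genes of different function. Scoc, a short coiled-coil protein, fell from 7.39 ± 1.03 to 1.82 ± 0.0425 RPKM (SD, n = 3 each), a log2 change of -1.57. It lies within 1 Mb of Ucp1 and is 1 of 16 called genes within 10 Mb of it. H2-Q10, a class I histocompatibility gene, fell from 72.1 ± 7.81 to 29.2 ± 9.19 RPKM, but it shares sequence with near-identical family members and its value is uncertain. Hsph1, a cytosolic heat shock protein, fell from 24.99 ± 12.4 to 9.32 ± 1.35 RPKM. Rbp4, the carrier of retinol, fell from 95.1 ± 5.83 to 48.2 ± 14.3 RPKM. Svip, an inhibitor of degradation at the endoplasmic reticulum, fell from 13.0 ± 1.41 to 6.02 ± 0.836 RPKM. The metallothionein Mt2 and the clock output gene Dbp also belong to this group and are described with their lists.

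Most tested genes of the integrated stress response, the programme driven by ATF4 when translation is restrained, were higher in knockout brown fat. Mthfd2, a mitochondrial enzyme of one-carbon metabolism, rose from 1.09 ± 0.407 to 9.98 ± 3.03 RPKM (SD, n = 3 each; log2 change 2.38, limma adjusted p = 0.000489). Trib3, a pseudokinase induced by ATF4, rose from 2.54 ± 0.378 to 7.13 ± 1.24 RPKM. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, rose from 3.67 ± 0.489 to 8.70 ± 1.09 RPKM. Of 24 tested members of this list, 16 rose, none fell and 8 did not pass, and 18 rose when adjusted over the list alone. The camera adjusted p was 8.48e-09, with an adjusted p = 0.334 with an estimated correlation. Directional fry gave an adjusted p = 0.00648 for the list. After median-of-ratios scaling 11 members passed. Without knockout replicate 1 or knockout replicate 2 the count was 10 members in each case. None of the 16 members was at least 2 times lower in wildtype replicate 3 than in each other wildtype library. Of the 20 muscle genes, 19 were. A gene that other cells also express can miss this criterion even if its rise comes from muscle. The criterion therefore cannot separate these members from muscle. Of 15 members of the unfolded protein response of the endoplasmic reticulum, Sel1l rose from 11.8 ± 0.243 to 18.2 ± 0.900 RPKM and Edem1 from 12.3 ± 0.733 to 16.5 ± 1.13 RPKM, and 13 did not pass (camera adjusted p = 0.564; 2 rose over the list alone and 1 after median-of-ratios scaling). The call on Edem1 was lost in 7 alternatives. Of 15 members of mitochondrial proteostasis, Clpx, a subunit of a matrix protease, rose from 33.9 ± 1.42 to 45.7 ± 1.44 RPKM and 14 did not pass (camera adjusted p = 0.895; 2 rose over the list alone).

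Few genes of the brown adipocyte programme other than Ucp1 passed. Of 24 tested thermogenic genes, 2 rose, 2 fell (Ucp1 included) and 20 did not pass. Ppara, a nuclear receptor for fatty acids, rose from 43.5 ± 4.85 to 65.4 ± 10.1 RPKM, and Prdm16, a regulator of brown fat identity, fell from 4.98 ± 0.822 to 3.24 ± 0.261 RPKM (SD, n = 3 each). Neither rise of the thermogenic list passed after median-of-ratios scaling, whereas 2 falls did. The call on Prdm16 was lost in 9 alternatives and that on Ppara in 8. Adjusted over the list alone, 3 thermogenic genes rose and 2 fell (camera adjusted p = 0.301). Without wildtype replicate 2, the wildtype library with the least Ucp1, this list tested lower as a set (camera adjusted p = 0.017). The list holds Ucp1 itself. With all 6 libraries its median log2 change was 0.1, and with Ucp1 left out the camera adjusted p was 0.648. Ucp1 was not left out in the fit without wildtype replicate 2, so that call does not show a fall of the other members. Of 17 genes tied to heat production without UCP1, 7 rose, 2 fell and 8 did not pass, with 8 and 3 when adjusted over the list alone and 5 and 2 after median-of-ratios scaling (camera adjusted p = 0.356). Directional fry, which does not compare a list with other genes, gave an adjusted p = 0.0459. The called members included Ryr1, the calcium release channel of muscle (0.495 ± 0.324 to 5.18 ± 0.699 RPKM), Ckmt2, the mitochondrial creatine kinase of sarcomeres (1.60 ± 1.13 to 18.8 ± 3.41 RPKM), and Atp2a1. These are also abundant in muscle fibres, and 3 of the 7 higher members followed the muscle list among wildtype libraries. Ucp2, a relative of Ucp1, rose from 7.77 ± 0.596 to 11.9 ± 0.460 RPKM.

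None of 53 tested nuclear genes of the respiratory chain passed limma's gene test, and none passed over the list alone, while 2724 genes in all reached an unadjusted p under 0.05. The member with the smallest p, Uqcrh of complex III, stood at 529 ± 25.8 RPKM in knockout and 630 ± 40.3 RPKM in wildtype (SD, n = 3 each). As a set, the respiratory chain list lay below other genes, with a median log2 change of -0.05 and a camera adjusted p of 1.17e-05, and an adjusted p = 0.669 with an estimated correlation. Median-of-ratios scaling gave a median of -0.15 and 1 lower member. None of 7 tested mitochondrially encoded genes passed (camera adjusted p = 0.390; none over the list alone). COX1 stood at 25910 ± 1850 RPKM in knockout and 25360 ± 1450 RPKM in wildtype. The rows for COX2, COX3 and ND3 held means under 10 RPKM in both groups, far below COX1, and are uncertain because nuclear copies of these genes exist. COX1, COX3 and ND3 lie outside the rule for named genes and were chosen after their values were seen. COX2, the member with the smallest p, stood at 5.32 ± 0.209 RPKM in knockout and 4.31 ± 0.550 RPKM in wildtype.

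Among genes of fuel use, most members of each list did not pass. Elovl6, which elongates palmitate, fell from 244 ± 32.9 to 154 ± 12.0 RPKM (SD, n = 3 each). It was the 1 member of 16 in de novo fatty acid synthesis to pass, with 2 lower over the list alone, a median log2 change of -0.35 and a camera adjusted p of 1e-06 (adjusted p = 0.669 with an estimated correlation). Median-of-ratios scaling gave 3 lower members of this list and a median of -0.45. Of 24 genes of fatty acid oxidation 3 rose, also over the list alone, and 21 did not pass (camera adjusted p = 0.683). Among them were Acot2, a mitochondrial thioesterase (14.3 ± 1.42 to 28.3 ± 4.40 RPKM), and Cpt1a, which admits fatty acids to mitochondria (2.97 ± 0.282 to 4.61 ± 0.265 RPKM). Of 20 genes of glucose uptake and glycolysis, 3 rose: the hexokinase Hk1 (7.98 ± 2.79 to 21.4 ± 0.571 RPKM), the phosphofructokinase Pfkm (26.2 ± 1.28 to 43.2 ± 4.33 RPKM) and the glucose transporter Slc2a1 (2.14 ± 0.188 to 3.36 ± 0.329 RPKM). Pfkm is also the phosphofructokinase of muscle. This glycolysis list nevertheless tested lower than other genes (camera adjusted p = 0.0357, adjusted p = 0.669 with an estimated correlation), with a median log2 change of -0.07 and a mean of 0.03. That call was lost after median-of-ratios scaling (adjusted p = 0.0993), with no filter on low values (0.0736), without knockout replicate 1 (0.0777) or 3 (0.258), and without wildtype replicate 2 (0.11) or 3 (0.0773). Over the list alone, 4 glycolysis genes rose and 3 fell, and after median-of-ratios scaling 3 rose and 2 fell. The call on Slc2a1 was lost in 7 alternatives.

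No gene passed among 23 of triglyceride storage and lipolysis (camera adjusted p = 0.547), 15 of cholesterol synthesis (0.115) and 15 of the citric acid cycle (0.648), whether over all genes or over the list alone. The cholesterol list tested lower as a set without knockout replicate 2 (camera adjusted p = 0.00475) and without wildtype replicate 1 (0.00992). The members with the smallest p were Angptl4, an inhibitor of lipoprotein lipase, at 75.1 ± 9.63 RPKM in knockout and 56.3 ± 6.35 RPKM in wildtype, Hmgcs1 at 70.9 ± 2.29 and 52.9 ± 9.44 RPKM, and Idh2 at 151 ± 14.8 and 119 ± 21.8 RPKM (SD, n = 3 each). Of 19 genes of branched-chain amino acid breakdown, Bckdhb rose from 49.4 ± 3.93 to 65.1 ± 3.5 RPKM and 18 did not pass (camera adjusted p = 0.702; 1 over the list alone). It did not pass in 8 alternatives, median-of-ratios scaling among them. Of 25 genes of purine metabolism, 2 rose, 23 did not pass, 3 rose over the list alone and 1 after median-of-ratios scaling (camera adjusted p = 0.576). These were Ampd1, the muscle AMP deaminase (0.664 ± 0.496 to 7.72 ± 0.0814 RPKM), which followed the muscle list among wildtype libraries, and Adssl1 (19.3 ± 3.26 to 27.5 ± 2.51 RPKM), whose call was lost in 14 alternatives.

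Clock genes changed in both directions. Per2, a repressor of the circadian loop, fell from 14.9 ± 1.21 to 7.10 ± 1.14 RPKM, and Dbp, a clock output factor, fell from 48.0 ± 11.6 to 22.0 ± 4.21 RPKM (SD, n = 3 each). Gm129, a further clock repressor, fell from 6.23 ± 0.338 to 3.27 ± 0.408 RPKM. Of 18 tested clock genes 5 fell, 2 rose and 11 did not pass, over the list alone 6 fell and 3 rose, and after median-of-ratios scaling 6 fell and 1 rose. The camera adjusted p was 7.27e-05, with an adjusted p = 0.481 with an estimated correlation. The labels give no time of day for tissue collection. Both metallothioneins of the antioxidant list fell, Mt1 from 258 ± 8.61 to 154 ± 9.75 RPKM and Mt2 from 97.9 ± 17.5 to 46.5 ± 6.87 RPKM. Both lie on the same chromosome as Ucp1, beyond 10 Mb from it. Whether DNA near the targeted allele bears on them was not tested. Hmox1, the inducible haem oxygenase, rose from 7.41 ± 0.726 to 17.4 ± 3.86 RPKM and is 1 of 16 called genes within 10 Mb of Ucp1, and 21 of the 24 antioxidant genes did not pass (camera adjusted p = 0.165; 2 rose and 2 fell over the list alone). None of 19 immediate early genes passed, also over the list alone (camera adjusted p = 0.702). Dusp1, the member with the smallest p, stood at 44.9 ± 8.38 RPKM in knockout and 27.0 ± 8.71 RPKM in wildtype.

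**Figure D2:**
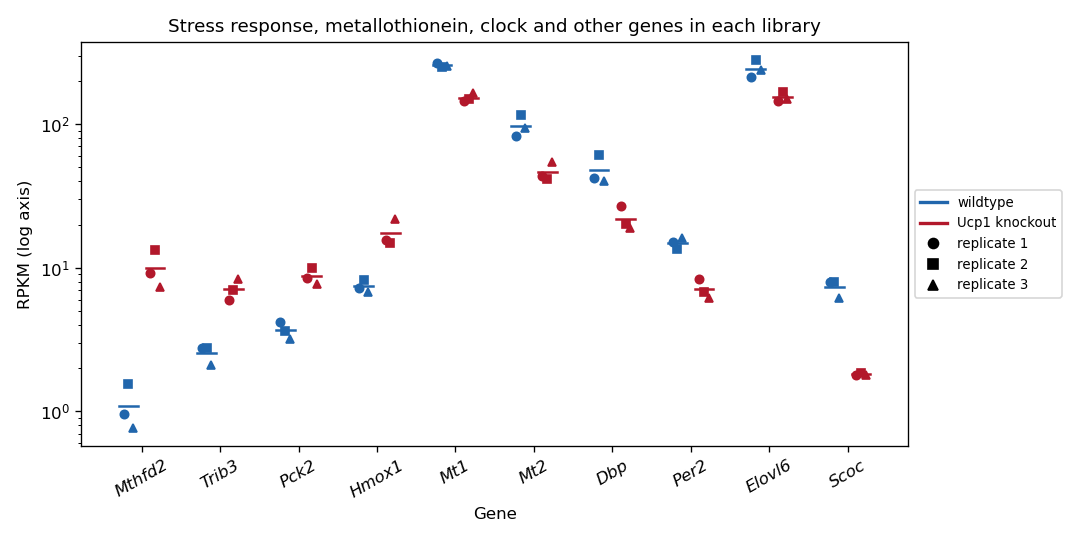
RPKM of 10 genes in each library on a log axis, with wildtype in blue, Ucp1 knockout in red, a symbol for each replicate and a horizontal line at each group mean. Mthfd2, Trib3, Pck2 and Hmox1 were higher in every knockout library than in any wildtype library, and Mt1, Mt2, Dbp, Per2, Elovl6 and Scoc were lower. Hmox1 and Scoc lie within 10 Mb of Ucp1, and Mt1 and Mt2 lie farther away on the same chromosome.

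Most markers of immune cells and stroma did not pass. Among macrophage markers, Mpeg1, a pore-forming protein, rose from 1.41 ± 0.353 to 3.44 ± 0.564 RPKM, and the class II histocompatibility genes H2-Ab1 and H2-Eb1 rose from 20.02 ± 1.90 to 31.2 ± 5.01 RPKM and from 18.3 ± 2.47 to 28.7 ± 4.56 RPKM (SD, n = 3 each). Of 20 tested macrophage markers 5 rose and 15 did not pass, while 17 rose over the list alone (camera adjusted p = 1.29e-05, adjusted p = 0.669 with an estimated correlation). After median-of-ratios scaling 2 macrophage markers passed, and the call on H2-Eb1 was lost in 7 alternatives. Of 21 interferon-stimulated genes, Gbp3 rose from 4.26 ± 0.174 to 6.65 ± 0.943 RPKM and Ddx58 from 3.18 ± 0.239 to 4.40 ± 0.249 RPKM, although the call on Ddx58 was lost in 11 alternatives. Of these interferon-stimulated genes 19 did not pass, 13 rose over the list alone and 1 after median-of-ratios scaling (camera adjusted p = 0.000205, adjusted p = 0.669 with an estimated correlation). Of 9 cytokine and chemokine genes, Ccl8 rose from 0.321 ± 0.251 to 1.97 ± 0.261 RPKM (camera adjusted p = 0.702; 2 rose and 1 fell over the list alone, and 1 rose and 1 fell after median-of-ratios scaling). Of 24 genes of the extracellular matrix 4 rose, 20 did not pass, 9 rose over the list alone and 2 after median-of-ratios scaling (camera adjusted p = 0.00256, adjusted p = 0.669 with an estimated correlation and 0.0773 without wildtype replicate 3). Examples were Loxl1, a collagen cross-linking enzyme (6.39 ± 1.99 to 12.0 ± 1.28 RPKM), Mmp14, a membrane collagenase (2.04 ± 0.211 to 3.70 ± 0.582 RPKM), and Sparc (297 ± 7.88 to 370 ± 7.35 RPKM), with the call on Loxl1 lost in 7 alternatives and that on Sparc in 11. None of the called members of these 4 lists followed the muscle list among wildtype libraries, a criterion that genes also expressed outside muscle can miss.

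Of the genes enriched in white adipocytes, a minority rose. Npr3, the clearance receptor for natriuretic peptides, rose from 7.16 ± 0.943 to 13.2 ± 2.06 RPKM, Hoxc8 from 1.41 ± 0.324 to 3.13 ± 0.332 RPKM, and Agt, which encodes angiotensinogen, from 0.546 ± 0.470 to 2.39 ± 0.994 RPKM (SD, n = 3 each). Of 15 tested members 5 rose, 10 did not pass, 7 rose over the list alone and 3 after median-of-ratios scaling (camera adjusted p = 0.00526, adjusted p = 0.669 with an estimated correlation and 0.0602 without knockout replicate 3). Of 13 secreted factors of brown fat, Epdr1 rose from 1.09 ± 0.529 to 3.98 ± 0.667 RPKM and Metrnl from 1.45 ± 0.165 to 2.36 ± 0.292 RPKM, Nrg4 fell from 72.9 ± 3.01 to 58.2 ± 3.28 RPKM, and 10 did not pass (camera adjusted p = 0.702; 6 rose and 2 fell over the list alone, and 1 rose and 2 fell after median-of-ratios scaling). The calls on Metrnl and Nrg4 were lost in 9 alternatives each, and that on Agt of the white adipocyte list in 6.

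**Figure D3:**
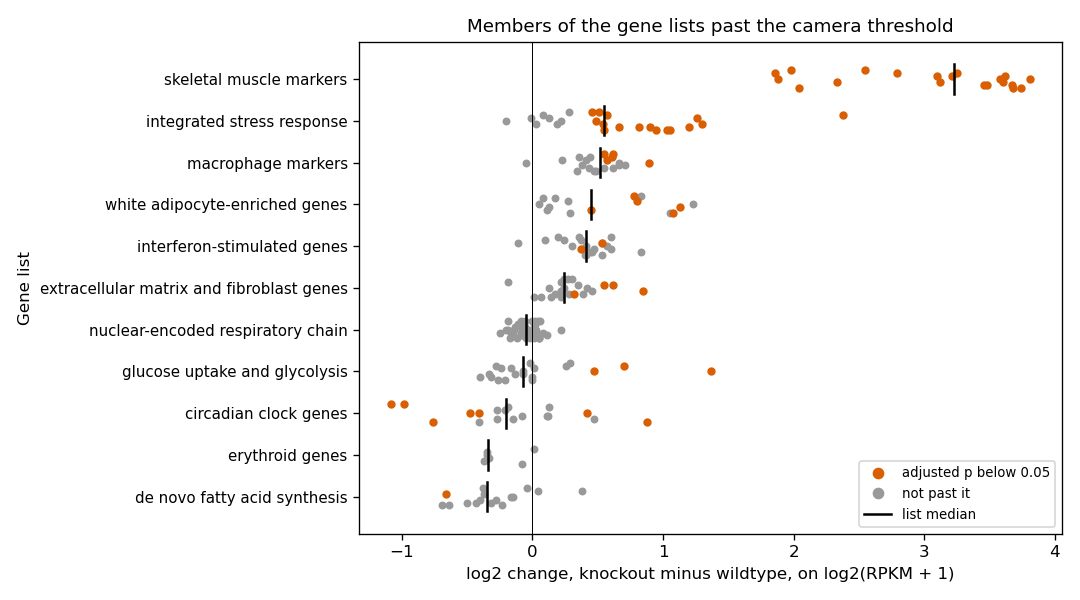
Log2 change between knockout and wildtype of each tested member of the 11 gene lists past the camera threshold, on log2(RPKM + 1), with members past the limma threshold in orange, others in grey and a black line at each list median. The skeletal muscle list lies apart at a median of 3.23, the integrated stress response follows at 0.55, and de novo fatty acid synthesis is lowest at -0.35.

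Markers of other cell types were measured as a check of tissue composition. Of 10 pericyte and smooth muscle markers Des, the intermediate filament desmin that skeletal muscle also holds, rose from 27.9 ± 3.90 to 55.1 ± 6.80 RPKM, also over the list alone, and 9 did not pass (camera adjusted p = 0.0894, and 0.0186 as a lower set without wildtype replicate 3). None of 16 endothelial markers (0.0803), 6 nerve and Schwann cell markers (0.702), 5 cell cycle genes (0.702) or 6 erythroid genes passed, also over the list alone. The endothelial list tested lower as a set without knockout replicate 1 (camera adjusted p = 0.007) and without wildtype replicate 2 (0.0269). The erythroid list tested lower as a set (camera adjusted p = 0.0357, adjusted p = 0.669 with an estimated correlation), with Hba-a1 at 61.8 ± 10.8 RPKM in knockout and 83.0 ± 29.4 RPKM in wildtype. That call was lost after median-of-ratios scaling (adjusted p = 0.18), with no filter on low values (0.0569), without knockout replicate 2 (0.0601) or 3 (0.16), and without wildtype replicate 2 (0.901). The members with the smallest p in the other 3 lists were Cldn5 at 14.5 ± 1.79 and 11.3 ± 0.563 RPKM, Prx at 1.33 ± 0.17 and 1.01 ± 0.575 RPKM, and Mcm7 at 2.88 ± 0.221 and 2.39 ± 0.192 RPKM, in knockout and wildtype (SD, n = 3 each). Of the lymphocyte markers 2 were tested, Ptprc at 1.29 ± 0.244 and 0.773 ± 0.146 RPKM and Ighm at 7.06 ± 0.709 and 4.004 ± 2.74 RPKM, and neither passed over all genes, while both passed over the list alone. No epithelial or keratinocyte marker reached the level needed for testing. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty did not pass, also over the list alone, with Ddx3y at 23.1 ± 0.341 RPKM in knockout and 22.7 ± 0.544 RPKM in wildtype, Eif2s3y at 32.9 ± 3.96 and 32.6 ± 2.42, Kdm5d at 3.60 ± 0.151 and 3.84 ± 0.376, and Uty at 4.61 ± 0.0163 and 4.17 ± 0.615 RPKM.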

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

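This result comes from data outside the comparison of genes, and its test was planned as an alternative. Of 1896 tested table rows with no gene identifier, 29 were higher and 7 lower in knockout than in wildtype libraries (limma, adjusted over all table rows). These rows have no gene name, so they were left out of the comparison of genes.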

How the results depend on the processing

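The alternatives with the highest row per gene and without muscle-following genes, and the heat shock list without wildtype replicate 3, were chosen after seeing the data, and all others before. The count of 894 changed genes became 394 with at least 5 RPKM in 3 libraries, where fewer genes are tested, 370 at an adjusted p of 0.01, 196 with a log2 change of at least 1, 3597 with a test for each table row, which holds several rows per gene, and 474 with limma-voom on recovered reads, where fewer genes are tested. Of the 894 genes, 461 entered the stricter filter and 394 of these passed, and 500 entered limma-voom and 356 of these passed. It ranged from 457 without knockout replicate 2 to 850 without wildtype replicate 2, and 445 and 680 of the 894 genes remained called in those fits. Under median-of-ratios scaling 578 of the 894 remained called and none changed sign. The replicate numbers are shared between groups but no label pairs them: deviations of same-numbered libraries correlated at 0.09, 0.04 and -0.02, and the replicate block gave 778 calls, 689 higher and 89 lower. Of 30 lists tested, camera called 11 and with an estimated correlation 0, while directional fry called 3, of which 2 were among the 11, and mixed fry, which tests another question, called 20. The 3 were the integrated stress response (fry adjusted p = 0.00648), skeletal muscle (0.0459) and heat production without UCP1 (0.0459). Fry does not compare a list with other genes, so a shift common to many genes can add to its directional calls. Camera calls on 4 lists were lost in some alternatives, and 4 further lists were called lower with 1 library left out, as given with those lists. The odds ratio for calls near Ucp1, 2.31, was 1.93 with no filter (exact p = 0.0531) and 2.43 with a log2 change of at least 1 (exact p = 0.0912), ranging over alternatives from p = 0.000561 to 0.118. It lay between 1.84 without knockout replicate 2 and 2.97 without wildtype replicate 1, and lost the threshold without knockout replicate 1 or 2; the cause was not tested. Of the 16 stress response members, 10 entered the fit with at least 5 RPKM in 3 libraries and 7 of these passed, and 9 entered limma-voom and 8 of these passed. At an adjusted p of 0.01 10 passed, with a log2 change of at least 1 it was 6, and with a replicate left out 10 to 15 of the list passed. Of 20 muscle genes 13 entered limma-voom, and all 13 passed. The log2 change of Ucp1 lay between -3.04 and -2.6 and passed in each alternative run on it. For 59 other named genes past the threshold, all 1017 values under up to 18 alternatives kept their direction, 867 passed and 150 did not. Alternatives that changed only the threshold kept the same fit, so direction could not change in them. Of the lost calls, 30 came from requiring a log2 change of at least 1, which is fixed by the main fit, and 20 from an adjusted p of 0.01. Adssl1 lost its call in 14 alternatives, Ddx58 and Sparc in 11 each, and Metrnl, Nrg4 and Prdm16 in 9 each. Bckdhb and Ppara lost it in 8 each, and Edem1, H2-Eb1, Loxl1 and Slc2a1 in 7 each. Agt lost it in 6, and H2-Ab1 and Hsph1 in 5 each. Ddx3y (0.02) and Eif2s3y (0.01), neither past the threshold, changed sign under median-of-ratios scaling (-0.07 and -0.09). Ddx3y was at 0.00 with rows summed, and Eif2s3y ranged from -0.05 to 0.11 with a replicate left out. The alternatives that need counts (TMM and RLE scaling, the quasi-likelihood and Wald tests) were not run, since the table holds none. Depth of 15800000 to 18000000 reads leaves genes near 1 RPKM with few reads.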

Other observations

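Several tests here were chosen only after results were seen: the count of muscle genes that vary among wildtype libraries, the heat shock list with and without wildtype replicate 3, the median of the stress response list after scaling, the count of genes that follow muscle, and the least-squares form of the slopes, which replaced a difference of means. Except for Hsph1 and Myl1, the genes named in this paragraph and the next, and the stress response genes named further on, lie outside the rule for named genes and were chosen after their values were seen. In the integrated stress response list, Phgdh and Psat1, the enzymes that open serine synthesis, stood at 1.39 ± 0.204 and 5.43 ± 2.13 RPKM in knockout against 0.35 ± 0.156 and 1.54 ± 0.426 RPKM in wildtype (SD, n = 3 each). Asns, which makes asparagine, rose from 28.8 ± 1.51 to 46.2 ± 2.91 RPKM. The factors Atf4 and Atf5 rose from 81.0 ± 12.9 to 114 ± 5.89 RPKM and from 86.7 ± 7.29 to 211 ± 40.9 RPKM. The call on Atf4 was lost after median-of-ratios scaling (limma adjusted p = 0.0814), while that on Atf5 stayed (0.00214). Psph of serine synthesis (limma adjusted p = 0.179) and the factors Atf3 (0.408) and Cebpg (0.0518) did not pass. In the clock list the activators Clock and Arntl rose, from 8.56 ± 0.783 to 11.8 ± 0.946 RPKM and from 0.587 ± 0.145 to 1.99 ± 0.790 RPKM. Nr1d1 and Tef fell, from 45.6 ± 3.84 to 32.6 ± 5.32 RPKM and from 65.4 ± 3.25 to 49.3 ± 5.21 RPKM. After median-of-ratios scaling 1 gene of the clock list passed as higher and 6 as lower.

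Of 23 listed chaperone genes, 4 were lower and 2 higher in knockout brown fat and 17 did not pass. Hspa8 fell from 71.6 ± 13.1 to 44.3 ± 1.11 RPKM, Hsp90ab1 from 344 ± 47.2 to 237 ± 12.2 RPKM and Hspb1 from 12.0 ± 1.69 to 8.37 ± 0.651 RPKM, beside Hsph1 (SD, n = 3 each). Over the list the median log2 change was -0.21, with 18 members below 0. The list's camera p was 2.7e-09, with p = 0.106 with an estimated correlation and p = 0.122 by fry, and it was written after Hsph1 had been seen and contains it. Wildtype replicate 3 was the highest library for 16 of the 23 genes: Hsph1 stood at 15.47, 20.47 and 39.03 RPKM in wildtype replicates 1, 2 and 3, and Dnajb1 at 12.3, 14.69 and 24.21 RPKM. Without that library 14 members lay below 0 with a median of -0.17, and 4 passed as lower. The 2 that rose, Cryab (11.6 ± 4.20 to 25.5 ± 4.41 RPKM) and Hspb8 (35.4 ± 7.72 to 59.1 ± 7.76 RPKM), are abundant in muscle fibres. Slow-fibre genes varied within the knockout group, with Myh7 at 6.82 ± 4.96 RPKM and Tnnc1 at 15.6 ± 11.1 RPKM. Of the 808 genes higher in knockout, 97 (12.0%) followed the muscle list among wildtype libraries, against 0.26% of genes not called, and 797 called genes did not follow it. This criterion misses muscle genes such as Myl1 and Tnnc1, so 797 is not a count free of muscle.

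Skeletal muscle genes were about as high relative to Acta1 between the groups as among wildtype libraries. If muscle tissue had been carried along in dissection, each gene would keep a fixed slope against Acta1, and the median ratio of the wildtype slope to the slope between groups was 1.02 over 19 genes (bootstrap interval over genes 0.97 to 1.12). These genes move together (estimated correlation 0.897), and every wildtype slope rests on the same 3 libraries. The interval thus measures agreement among genes, not spread over libraries. The ratio is what carried muscle predicts, so carried muscle is a candidate explanation. Muscle genes switched on in knockout brown adipocytes remain open: 19 of the 20 members also differed by 2-fold or more among wildtype libraries, but the bound of all 20 was set after this count was seen, so the count decides nothing. The design confounds the amount of muscle with genotype, because all 3 knockout libraries held more than every wildtype library.

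Genes near Ucp1 were called more often than other genes, a test fixed before the data were examined. Within 10 Mb of Ucp1, 16 of 98 tested genes were called (16.3%), against 7.8% elsewhere (odds ratio 2.31, Fisher's exact p = 0.00426, two-sided). Without knockout replicate 1 or 2 the odds ratio was 2.04 or 1.84 and no longer passed (exact p = 0.0686 and 0.118). The 2 smallest p-values among them belonged to Rnf150, which fell from 3.57 ± 0.0852 to 0.506 ± 0.0557 RPKM (SD, n = 3 each; limma adjusted p = 0.000121), and Scoc. Hmox1 of the antioxidant list is also among the 16. Of the 16, 5 were lower and 11 higher, against 77 lower and 781 higher among calls elsewhere. The odds ratio of a lower call was 4.6 (interval 1.22 to 14.81, Fisher's exact p = 0.0123), a comparison outside the written plan. Of the 259 windows of 20 Mb over the genome, 1.5% held as high a share of called genes. These windows were placed every 10 Mb, so they overlap, and some cover the region of Ucp1. Donor-strain DNA flanking the targeted allele is a candidate explanation, but any local cluster of calls would give such a share. An effect of the allele on close neighbours alone stays open. Within 1 Mb, 9 of 26 genes were called, 4 lower and 5 higher (odds ratio of a call 6.26, interval 2.45 to 14.89). At 1 to 10 Mb, 7 of 72 were called, 1 lower and 6 higher. This was 9.7% against 7.8% elsewhere (odds ratio 1.27, interval 0.49 to 2.79, Fisher's exact p = 0.507). That interval holds both no excess and a clear one. Fisher's exact test treats genes as independent, but all were measured in the same 6 libraries and can move together. Its p-values and intervals may thus be too narrow.

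Of 24 integrated stress response genes 16 rose, with muscle RNA higher in the same libraries, and library scaling and muscle were weighed as their source. Over all 24 members the median log2 change was 0.55 as deposited (bootstrap interval over genes 0.28 to 0.90). After median-of-ratios scaling it was 0.47 (0.18 to 0.83). The list's camera adjusted p after scaling was 2.23e-10 at the preset correlation (as deposited 8.48e-09, and adjusted p = 0.334 with an estimated correlation). Camera compares the list with other genes, so a factor common to a library could hardly end that call. The scale factors were 1.029 to 1.048 in knockout and 0.953 to 0.977 in wildtype libraries, too alike to remove a median of 0.55. The criterion, written after the value was seen, could thus hardly have come out otherwise. Scaling of this size is argued against as the whole cause by the size of the factors alone. After scaling, the list's mean log2 value lay 0.49 to 0.61 above the wildtype mean in the knockout libraries and within 0.04 of it in the wildtype libraries. The same scaling moved the count of changed genes from 894 to 645. The members called fell from 16 to 11, between the bounds set beforehand for and against scaling. In the 5 that were lost, the median log2 change went from 0.51 to 0.41 with a median SE of 0.12 in both fits (adjusted p = 0.0564 to 0.131). With fewer genes called, the largest unadjusted limma p that passed went from 0.00387 to 0.00277. Of the 5, 4 had an unadjusted p above both limits as their change shrank, the SE of Nupr1 and Vldlr also rising slightly, and Chac1 had one between them, so its call ended with the stricter limit as well. The median slope ratio of the 16 called members was 0.67 (bootstrap interval over genes -0.71 to 1.4), which is too wide to exclude muscle or to point to it. A response of brown adipocytes to the loss of Ucp1 is a further hypothesis that the design names and these libraries could not separate from muscle.

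The real split of the 6 libraries called 894 genes and the highest of the other splits called 0, so 1 of 10 splits gave as many. With 10 splits a share under 0.05 cannot be reached.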
